A study of Mus musculus with 6 samples.

How the data were processed

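The series measured polyadenylated RNA from pooled mouse neocortex, in libraries made with a stranded mRNA kit per the labels' protocols. The submitters' processing notes name FastQC, TopHat2 2.0.13, Bowtie2 2.2.3, HTSeq 0.6.1p1 and the mm10 build, without their order or settings. The gene annotation and the strand setting are not given in the sources used here. The deposited table has a column of gene names and 6 value columns, per the file header.

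The value columns were matched to no sample, because their names match no sample title and no label pairs them. All 6 were left out of every result. While the table was being inspected, before this was recognised, column totals and the values of a few genes were seen, Tshz3 and sex-linked genes among them, and no group was assigned from them. The planned test of mutant against wild-type libraries, its gene list tests and its alternatives were not run. Depth and replicate spread are for the same reason not reported.

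The gene names were compared with the symbols of GENCODE M21 and of the RefSeq table of GRCm38.p6, the assembly on which mm10 is based, by exact match of the whole name. Coordinates are those of GENCODE M21. The gene lists were written before the data were examined.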

Results

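RNA was sequenced from the neocortex of mice at postnatal day 34. The labels describe 6 pools of cortices, 3 from mice mutant for Tshz3 and 3 from wild-type mice. Tshz3 encodes a zinc finger transcription factor of the teashirt family. The design implies a single comparison, mutant against wild-type cortex, and the series title places it in the setting of autism spectrum disorder.

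The comparison was not made. The 6 value columns of the gene table carry names that match no sample title, and neither the labels nor the table's header pair a column with a genotype. The name under which the table was deposited mentions the mutant before the control group, without saying which columns belong to either. Column order was not taken as evidence of genotype, and genotypes were not assigned from measured values such as the level of Tshz3. No expression level, depth per sample, fold change or test is therefore reported for any gene, Tshz3 included, and the values behind these columns were not used here.

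The names in the table's gene column could be described without any sample. The table held 23420 gene rows, each with a distinct name. Of these names, 21988 were current symbols in GENCODE M21 or RefSeq. The GENCODE symbols among them numbered 21785, of which 19338 belonged to protein-coding genes and 2447 to genes of other types. The protein-coding names made up 87.9% of the protein-coding names in GENCODE M21. These are exact matches of current symbols, so a gene listed under an older symbol is not counted, and the share of genes covered can be higher. With RefSeq synonyms added, 23303 names matched. Names beginning with mt-, the GENCODE style for genes encoded in mitochondrial DNA, numbered 0. Other naming styles for these genes were not searched, so their absence was not shown, and they were not analysed here. The counts describe listed names and say nothing about whether a gene was expressed in cortex.

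All 3 teashirt family genes were listed. In the GENCODE M21 annotation of GRCm38, Tshz3 lies on the plus strand of chromosome 7 from 36698118 to 36773553. Tshz1 lies on the minus strand of chromosome 18 from 84011627 to 84087706, and Tshz2 on the plus strand of chromosome 2 from 169633013 to 170071816. Each is annotated as protein coding.

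The gene lists fixed for the planned comparison were also matched by name. They held 773 entries, a gene in several lists or under an older and a newer symbol being entered more than once, and 757 entries were among the listed names. All 28 glutamate receptor and auxiliary subunit names were listed, as were all 41 names of the presynaptic release machinery and all 22 names of upper-layer projection neuron identity. Among the deep-layer projection neuron names, 29 of 31 were listed. The autism-associated list had 64 of its 69 entries among the listed names. In the lists for other cell types, all 24 astrocyte, 25 oligodendrocyte and 21 microglia names were listed. Of all protein-coding names in GENCODE M21, 87.9% were listed. That share counts exact GENCODE symbols only, whereas some lists also hold older symbols, so the list counts cannot be compared with it directly. A listed marker name says nothing about whether the cell type was in the dissected tissue. The listed names held 27 of 28 GABAergic interneuron markers, 9 of 11 blood cell names and 19 of 20 striatal medium spiny neuron names. Those not listed were Dlx6os1 among the interneuron markers, Hbb-bs and Hbb-bt among the blood names, and Drd1 among the striatal names. Drd1a, the older symbol of Drd1, was on the striatal list and was listed. The beta-globin names Hbb-b1 and Hbb-b2 were on the blood list and were listed.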

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

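The number of names matched to an annotated gene was 21988 with current GENCODE M21 and RefSeq symbols. It was 21785 with GENCODE M21 symbols alone and 23303 with RefSeq synonyms added, which left 117 names matched by none. Each wider set contains the narrower, so the count could only stay or rise as sources were added. A synonym was not checked to belong to a single gene. The name matching was not part of the planned comparison. Its main setting and both alternatives were chosen after the table was seen. The alternatives planned for the comparison of genotypes, including leaving out each replicate, were not run. No paired analysis was possible because the value columns were matched to no sample and carry no replicate number from the labels.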
